A study of Mus musculus with 15 samples.

How the data were processed

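RNA of the olfactory bulbs of 15 male mice in 3 groups of 5 was measured on 1-colour Agilent mouse arrays, 1 array per mouse, on 2 slides. Per the labels' protocols, total RNA was extracted with TRIzol and treated with DNase I, and 100 ng was labelled with Cy3 by a low input amplification kit. Per the labels, each group holds 5 separate mice. The scanner files hold the intensity of each spot, which per the file headers came from Agilent Feature Extraction 10.7.3.1 with background subtraction and detrending within each array, dim spots being given a surrogate value, and without scaling between arrays. Other columns hold flags that, per the file headers, the same program set for each spot. The authors' series values hold the processed intensity of each spot divided by the array's median over all 59305 spots that are not controls, as found by setting each column against its scanner values. They are linear, and the column medians lie between 0.899 and 0.935. Probe coordinates are those of mouse build mm9, per the file headers.

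Each array had 62976 spots. Control spots and spots with an outlier flag were left out, 0 spots were saturated, log2 of the processed signal was taken minus the array's 75th percentile, and spots of a probe were averaged. A probe was kept if well above background on at least 4 of the 5 arrays of any group, which left 33965 of 55681 probes. A gene was represented by its kept probe with the highest mean, and 5182 genes had several. Gene names came from RefSeq names matched through accessions for 27509 probes, which changed 2017 symbols, and otherwise from the array design. Of 27441 genes tested 17606 had a gene symbol and 9835 only a transcript or probe name.

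The 3 comparisons were fitted together over all 15 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Gene lists, 33 in all and 32 with at least 5 tested genes, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The test was run again with the correlation estimated from the data, and with limma's fry, which asks whether a list's genes move one way on balance and compares them with no other genes. Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named Crhr1 and Crh, the 10 largest rises and 10 largest falls with a gene symbol in each comparison, the 5 genes with the largest opposed changes, and up to 4 genes of smallest p in each list that was called or held a called gene. Genes named outside that rule were chosen after their values were seen. Some genes that the rule names are not reported here. Where a gene was not well above background on any array of a group, its fold is a lower bound, the brighter group's mean against the mean of, per array, the higher of the dim probe's own signal and the lowest signal among probes well above background.

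Slide was tested as a fixed block, as a random block and within each slide. With a fixed block, the knockout change equals that among slide 1 arrays and the active CRHR1 change that among slide 2 arrays, so these differ from within-slide results only in their tests. Other alternatives were quantile normalization, normexp background correction with an offset of 50, the authors' scaled values, median centring, other filters and probe choices, a fit of the 2 groups compared, an intensity trend, array weights, stricter thresholds, the replicate number as a block, and each array left out in turn. The steps were tested on simulated data of 27441 genes with log2 changes of 0.5, 1 and 2. Simulated genes varied independently of each other and slides did not differ, so the simulated share of false calls need not hold for the real arrays. Recovery was 47.8%, 79.1% and 97.0% for knockout against Cre GFP, 47.8%, 79.1% and 98.5% for active CRHR1 against Cre GFP, and 47.0%, 81.2% and 96.1% for active CRHR1 against knockout, and 6.29%, 6.01% and 4.19% of the calls were false. Tables were read with the data.table package, version 1.17.8, and pandas 2.3.3, and figures drawn with matplotlib 3.10.9 in Python 3.11.15.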

Results

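The series profiled gene expression in mouse olfactory bulbs in which local signalling by corticotropin-releasing hormone (CRH), a stress peptide, through its receptor CRHR1 had been lowered or raised. Each of 15 male mice, aged 6 to 8 weeks, gave 1 sample of bulb RNA and 1 array. The bulbs had received 500 nL of an adeno-associated virus 2 weeks earlier. The viral cargo is expressed only in cells that contain Cre recombinase. In the knockout group 5 mice lacked CRHR1 and received a virus coding for green fluorescent protein (GFP), and the labels rank this group as low in CRH signalling. In the Cre GFP group 5 mice with Cre in CRHR1-positive granule cells, the main inhibitory neurons of the bulb, received a GFP virus and stood in for wild type. In the active CRHR1 group 5 mice with the same Cre line received a virus coding for a constitutively active CRHR1, and the labels rank this group as high.

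The labels give the strain 129S4/SvJae for the knockout mice and C57Bl/6 for the others, so that strain and loss of the receptor cannot be told apart in any comparison with the knockout group. The sample titles name Cre for the other groups only. Cre and the expression of viral GFP may therefore differ as well, and cannot be told apart from these either. Slide 1 held the 5 knockout arrays and Cre GFP arrays 1 to 3, and slide 2 held Cre GFP arrays 4 and 5 and the 5 active CRHR1 arrays. The 75th percentile of the signal lay between 664 and 1171 on the 15 arrays, and 58.7% to 66.9% of the probes were well above background. Mean correlations of an array with the others of its group ran from 0.985 to 0.993. Levels are log2 signals minus the array's 75th percentile, given as mean ± SD (n = 5). Changes are differences of these means, given as log2 change ± SE with the adjusted p of limma. With arrays centred on their median instead, changes shifted by -0.055 for knockout against Cre GFP, -0.097 for active CRHR1 against Cre GFP and -0.042 for active CRHR1 against knockout (medians over genes). The number of arrays limits the precision of every value.

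The targeted gene was lower in the knockout group but was not lost. Crhr1 had a level of 3.16 ± 0.12 in the knockout, 3.63 ± 0.18 in the Cre GFP and 3.72 ± 0.12 in the active CRHR1 group (chromosome 11, 104036691 to 104036750, mm9). It fell by 0.47 ± 0.09 in the knockout (adjusted p = 0.0140) and differed by 0.09 ± 0.09 between active CRHR1 and Cre GFP (adjusted p = 0.547), or by -0.01 with arrays centred on their median. A second Crhr1 probe (104036182 to 104036241) gave -0.47 and 0.08. Where these probes lie relative to the deleted part of the gene and to the viral coding sequence was not determined, and a probe outside either checks nothing about the label. Under the slide block the Crhr1 changes were -0.56 (adjusted p = 0.0152) and 0.22 (adjusted p = 0.250), and among slide 1 arrays alone the knockout change had the same size and an adjusted p of 0.0939. Without knockout arrays 2 and 5, left out after the data were seen, it was -0.48 (adjusted p = 0.0618).

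Crh itself, the ligand, was lower where the receptor was active. Its level was 2.43 ± 0.39 in the Cre GFP and 1.58 ± 0.18 in the active CRHR1 group (chromosome 3, 19593482 to 19593541), a fall by 0.85 ± 0.18 (adjusted p = 0.00954; with slide as a block -1.14, adjusted p = 0.00998). In the knockout group the level was 1.79 ± 0.28, and the difference from Cre GFP of -0.65 missed the threshold (adjusted p = 0.0625). Crhbp, which binds and neutralises CRH, fell by 0.70 ± 0.14 in the knockout (adjusted p = 0.0152), a call lost with slide as a block (-0.58, adjusted p = 0.0816). Its change in the active CRHR1 group was 0.10 (adjusted p = 0.668). The second receptor gene, Crhr2, showed changes of 0.01 and -0.02 (adjusted p = 0.986 and 0.953).

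The comparison of knockout with Cre GFP bulbs asks what lower CRH signalling goes with, but it also spans both strains. A few genes differed greatly. Gbp2b, an interferon-inducible GTPase (chromosome 3, 142281466 to 142281525), was well above background on all 5 knockout arrays and on 0 Cre GFP arrays, and was at least 13-fold higher (adjusted p = 0.000286). Cxcl1, a chemokine that attracts neutrophils, was at least 2.46-fold higher, also with 0 Cre GFP arrays above background (adjusted p = 0.00371). Fam227b rose by 2.86 ± 0.38, the protease gene Tmprss11d by 2.76 ± 0.46, Cnmd by 2.48 ± 0.47 and Card9, an adaptor of innate immune receptors, by 2.42 ± 0.36. Pttg1, which encodes securin (chromosome 11, 43233801 to 43233860), fell by 3.42 ± 0.22 (adjusted p = 3.38e-06). It stands on the list of genes known to vary between mouse strains. Dlk1, an imprinted Notch ligand, fell by 2.37 ± 0.16 (adjusted p = 4.92e-06). The corneal keratin gene Krt12 was at least 16.4-fold lower (adjusted p = 0.0153), with 0 knockout and 4 Cre GFP arrays above background. Other large falls were those of Eps8l1 (-3.44 ± 0.64), Zfp296 (-2.57 ± 0.22), Tti2 (-2.46 ± 0.23), Vmn2r29 (-1.96 ± 0.18) and Etnppl (-1.95 ± 0.23). These calls held when any 1 of the 15 arrays was left out. In the fit with the slide block all but Cnmd kept them (adjusted p = 0.0704).

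In all, 929 of 27441 genes passed the test, 537 higher and 392 lower in the knockout, and 74 higher and 76 lower by at least 2-fold. The 2 groups' arrays did not overlap for 784 of them (84.4%). Chance gives 0.794% for genes not selected. These genes were picked for a small p, which itself favours such separation, so the 2 shares cannot be compared. The count was 384 with slide as a block, 342 of them shared, and 115 on slide 1 alone. It fell to 544 without knockout array 2, 461 without knockout array 4, 471 without Cre GFP array 3 and 433 without Cre GFP array 4. The share of higher calls was 57.8%, and 33.5% of 406 calls with arrays centred on their median or 33.3% of 459 in the authors' scaled values, and 42.6% without knockout arrays 2 and 5, left out after the data were seen. The calls of 6 further genes among the largest changes were less firm. Zfp42 (3.77) lost its call in 9 of the 15 omissions (adjusted p up to 0.111), Spib (2.06) in 7 (up to 0.0844), Wfdc21 (1.86) in 6 (up to 0.0740) and Ppcdc (-2.11) in 12 (up to 0.0973). Hist2h2bb (3.33) lost it without knockout array 4 (adjusted p = 0.050), and Samd11 (-1.87) without knockout array 4 or Cre GFP array 4 (up to 0.0531). With slide as a block all 6 lost their calls (adjusted p from 0.0559 to 0.201), as did Zfp42 and Spib with median centring.

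Among the gene lists, genes of blood vessel walls and of olfactory ensheathing glia, the glia that wrap olfactory axons, were higher in the knockout. Of 15 endothelial and mural genes 4 rose and 0 fell: the pericyte genes Rgs5 by 1.03 ± 0.15, Kcnj8 by 0.96 ± 0.13, Abcc9 by 0.95 ± 0.11 and Pdgfrb by 0.31 ± 0.07 (6 rose adjusted over the list alone; list median 0.19, adjusted p = 8.36e-05). Of 10 ensheathing glia genes 4 rose and 0 fell, among them Ngfr by 0.75 ± 0.11 and Npy by 0.53 ± 0.10 (6 adjusted over the list alone; median 0.25, adjusted p = 0.000399). These 2 lists passed limma's fry (adjusted p = 0.0171 and 0.0272) but not camera with an estimated correlation (adjusted p = 0.835 for both). Of 15 cell cycle genes 2 rose (6 adjusted over the list alone; median 0.39, or 0.29 with members below background at their bound; adjusted p = 0.000183): Ccnd2 by 0.56 ± 0.07, and Bub1, which was not well above background in either group. Granule cell markers were lower (median -0.14, adjusted p = 0.00373), with 1 of 18 fallen, Etv1 by 0.35 ± 0.07, and 1 higher and 3 lower adjusted over the list alone. Blocked on slide, the medians of these 4 lists were 0.20, 0.32, 0.26 and -0.11, and all kept their call. With an estimated correlation, adjusted p = 0.835 for the last 2 lists as well. The calls of Pdgfrb and Etv1 were lost in 5 (adjusted p up to 0.0808) and 4 (up to 0.0529) of the 15 omissions, with slide as a block (0.0505 and 0.102) and, with that of Npy, with median centring.

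Immune and myelin lists were also shifted up in the knockout. Microglia genes (15 tested, median 0.27, adjusted p = 0.00121), antigen presentation genes (13 tested, 0.54, adjusted p = 0.00210) and interferon response genes (21 tested, 0.52, adjusted p = 0.0267) had 0 members past the threshold in limma, also adjusted over the list alone, although 15, 13 and 20 of the members had higher means and 3, 4 and 3 were higher at an unadjusted p under 0.05. Of 14 oligodendrocyte genes 1 rose, Mbp by 0.41 ± 0.10 (2 adjusted over the list alone; median 0.18, adjusted p = 0.0267), while its other probes gave -0.26 and -0.20. With slide as a block, and among slide 1 arrays alone, the medians were 0.20 for microglia, 0.27 for antigen presentation, 0.17 for interferon response and 0.27 for oligodendrocyte genes. The block ended the calls of antigen presentation (adjusted p = 0.114, and 0.00823 within slide 1) and interferon response (0.487, and 0.376 within slide 1). The interferon call was also lost without knockout array 3 (median 0.28, adjusted p = 0.455) or 5 (0.101) or Cre GFP array 1 (0.0511), 4 (0.0861) or 5 (median 0.33, adjusted p = 0.213). The oligodendrocyte call was lost without knockout array 4 (0.0672) or 5 (median 0.10, adjusted p = 0.112) or Cre GFP array 1 (median 0.12, adjusted p = 0.0940) or 2 (0.126), and the Mbp call in 10 of the 15 omissions (up to 0.110), with the block (0.0979) and with median centring. For all 8 shifted lists, adjusted p = 0.835 with an estimated correlation.

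The other 24 lists were not shifted in the knockout, but some held changed members. Of 15 growth factor genes Igfbp5 rose by 0.61 ± 0.06 (adjusted p = 0.000250), Cntf by 0.54 ± 0.08 and Igfbp2 by 0.37 ± 0.08, while Nrg1 fell by 0.47 ± 0.08 (list adjusted p = 0.330, median -0.01, mean 0.14; 4 rose and 1 fell adjusted over the list alone). Of 23 targets of cAMP and CREB, the pathway that CRHR1 activates, 4 fell, among them Pde10a by 0.47 ± 0.09 and the peptide gene Adcyap1 by 0.49 ± 0.11 (5 adjusted over the list alone; median -0.07, adjusted p = 0.0678). Under the slide block this list had a median of 0.00063 (adjusted p = 0.263). Of 27 presynaptic genes Snap25 fell by 0.98 ± 0.19 and Stx1a rose by 0.33 ± 0.08 (1 rose and 3 fell adjusted over the list alone; adjusted p = 0.165). Of 19 glucocorticoid response genes Sult1a1 fell by 1.30 ± 0.15, Plin4 fell by 1.37 ± 0.34 and Pdk4 rose by 0.42 ± 0.08 (2 rose and 5 fell adjusted over the list alone; adjusted p = 0.271). Of 28 genes beside Crhr1 on chromosome 11, Itgb3 fell by 0.72 ± 0.13 and C1ql1 rose by 0.56 ± 0.11, besides 2 further rises (3 rose and 4 fell adjusted over the list alone, and the list had an adjusted p = 0.430). Over all genes 929 of 27441 passed. The list test looks for a shift in 1 direction, so it could miss changes both ways beside Crhr1. Of 20 genes known to vary between mouse strains Pttg1 alone passed (1 fell adjusted over the list alone; adjusted p = 0.687; median 0.04, mean -0.06, test down). With slide as a block Pde10a (adjusted p = 0.0779), Adcyap1 (0.130), Igfbp2 (0.0856), Stx1a (0.116), Plin4 (0.0559) and Pdk4 (0.0615) lost their calls. Adcyap1 was also lost in 5 of the 15 omissions (adjusted p up to 0.0691), Igfbp2 in 4 (up to 0.0645), Stx1a in 8 (up to 0.0973) and Plin4 in 13 (up to 0.0875). Median centring ended the calls of Adcyap1, Cntf, Igfbp2, Stx1a, Pdk4 and C1ql1.

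Among the remaining lists, 0 immediate early genes of 24 passed in limma (1 at an unadjusted p under 0.05, list median 0.20, list adjusted p = 0.177). Changed members were Homer3 (0.44), Dlgap2 (-0.38) and Grin2c (-0.37) of 36 excitatory postsynaptic genes (median -0.05, adjusted p = 0.204), Gabrg1 (0.43) and Gabra5 (-0.39) of 20 GABA synapse genes (median -0.06, adjusted p = 0.0678) and Rapgef3 (-0.27) of 27 cAMP pathway components (median 0.04, adjusted p = 0.980). Second probes gave -0.0015 for Homer3 and 0.01 for Dlgap2. Glial and stress lists with changed members were astrocytes (Aqp4 0.34 and Slc1a3 0.37, of 12), oligodendrocyte precursors (Bmp4 0.32, Sox10 0.31 and Neu4 -0.42, of 8), reactive glia (Osmr 0.63 and S1pr3 0.54, of 10), apoptosis (1 lower, of 16), heat shock (Hspa1a -0.37, of 9) and neuropeptides (Npy and Adcyap1, of 17). Lists with 0 of their members past the threshold were T cells (median 0.36), mitral and tufted cells (0.00), dopaminergic periglomerular cells (-0.06), migrating neuroblasts (-0.04), cortical and anterior olfactory neurons (0.08), sensory neurons (0.01), blood (-0.02) and choroid plexus (0.02). The list tests gave adjusted p from 0.0678 to 0.999. Adjusted over the list alone, genes higher and lower were 1 and 3 for excitatory postsynapse, 1 and 5 for GABA synapse, 0 and 2 for cAMP components, 3 and 1 for astrocytes and for reactive glia, 2 and 1 for oligodendrocyte precursors, 1 and 2 for neuropeptides, 0 and 1 for apoptosis, heat shock and choroid plexus, 1 and 0 for blood, and 0 for the rest. Median, mean and test differed in sign for choroid plexus (mean -0.01, test down), sensory neurons (mean 0.09, test down), blood (mean 0.10, test up), migrating neuroblasts (mean 0.0044, test down) and apoptosis (median 0.07, mean -0.01, test up). With arrays centred on their median reactive glia passed (median 0.17, adjusted p = 0.0186). Of these genes Homer3, Hspa1a and Npy kept their calls with slide as a block, and with Dlgap2, Grin2c and Gabrg1 in all 15 omissions, the others being lost in 2 to 13 omissions (adjusted p up to 0.117). With arrays centred on their median the calls of Homer3, Dlgap2, Grin2c, Gabrg1, Gabra5, Rapgef3, Aqp4, Slc1a3, Bmp4, Sox10, Neu4, Osmr, S1pr3, Hspa1a, Npy and Adcyap1 were lost.

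The comparison of active CRHR1 with Cre GFP bulbs asks what higher CRH signalling goes with, in 1 strain. Car6, a secreted carbonic anhydrase (chromosome 4, 149561160 to 149561219), was at least 29.6-fold higher, well above background on 5 active CRHR1 and 0 Cre GFP arrays (adjusted p = 1.22e-06). The chemokines Cxcl9 and Cxcl10, which attract activated T cells, rose by 5.45 ± 1.02 and 4.38 ± 0.80. Cst7, a cystatin of activated microglia (chromosome 2, 150404490 to 150404549), rose by 5.41 ± 0.48 (adjusted p = 9.64e-05), and Acod1, which makes itaconate in activated macrophages, by 5.09 ± 0.65. Serpina3f (4.85 ± 0.62), the class I gene H2-Q5 (4.50 ± 0.55) and the interferon-induced GTPase Tgtp1 (4.32 ± 0.69) rose as well. Tgtp1 was well above background on only 2 of 5 Cre GFP arrays, so the size of its rise is uncertain. Falls were smaller. Among them were Npy2r, a receptor for neuropeptide Y (at least 1.47-fold lower, above background on 0 active CRHR1 and 2 Cre GFP arrays), Prdm8 (at least 1.53-fold lower), Tafa1 (-1.52 ± 0.25), Tmco5 (-1.42 ± 0.25), the Wnt inhibitor Wif1 (-1.12 ± 0.18), the sodium channel gene Scn10a (-1.10 ± 0.23) and Nell2, a secreted neuronal glycoprotein (-1.15 ± 0.11, adjusted p = 0.000142; chromosome 15, 95050575 to 95059563). These calls held in all 15 omissions and with slide as a block. Those of Htr2c (-1.58 ± 0.30), Mas1 (-1.10 ± 0.22) and Grp (-1.41 ± 0.31) were lost with the block (adjusted p = 0.0627, 0.0793 and 0.144), as was that of Ubd (4.42 ± 1.07; 0.0648), which was also lost in 5 of the 15 omissions (up to 0.0618). Cxcl13 (5.31 ± 1.23), also above background on only 2 of 5 Cre GFP arrays, was lost without Cre GFP array 5 or active CRHR1 array 1 (up to 0.0535).

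**Figure D1:**
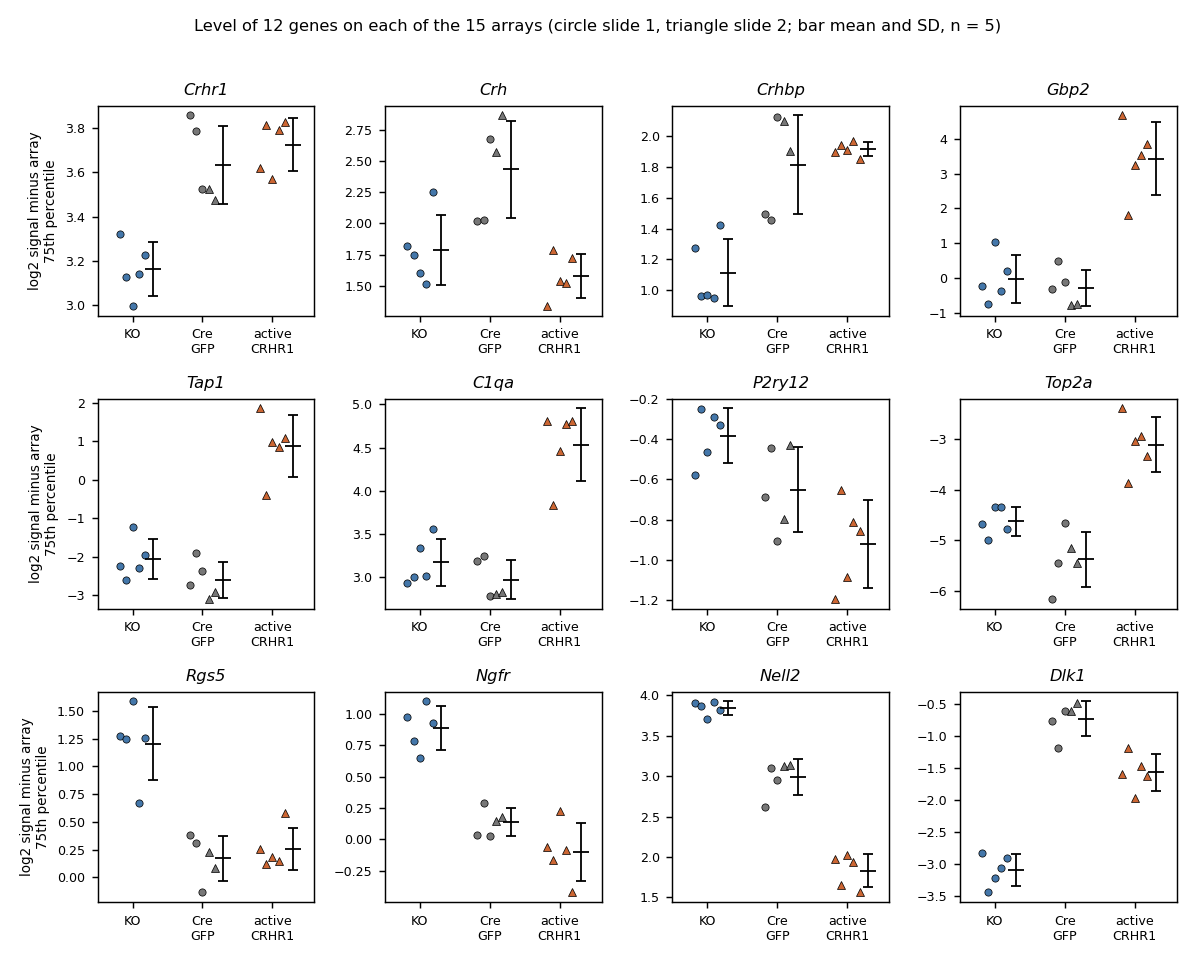
Levels of 12 genes on each of the 15 arrays by group, as log2 signal minus the array's 75th percentile; circles are slide 1, triangles slide 2, and bars the mean and SD (n = 5). Gbp2, Tap1 and C1qa are higher in the active CRHR1 group, Rgs5 and Ngfr are higher in the knockout group, Dlk1 is lower there, and Nell2 steps down from knockout to Cre GFP to active CRHR1.

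In all, 2339 genes passed, 1066 higher and 1273 lower with active CRHR1. By at least 2-fold, 580 were higher and 27 lower. The groups' arrays did not overlap for 1737 of them (74.3%). The count was 1018 with slide as a block, 903 of them shared, and 328 on slide 2 alone. It rose to 3671 without Cre GFP array 1 and fell to 1476 without Cre GFP array 3, 1243 without Cre GFP array 5, 1191 without active CRHR1 array 1 and 1421 without active CRHR1 array 5. The share of higher calls was 45.6%, and 56.1% of 1273 calls with arrays centred on their median, 65.9% with slide as a block, 78.7% on slide 2 alone, 65.0% with no filter on dim probes and 34.0% with array weights. It ran from 37.5% to 62.5% over the 15 omissions.

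Every tested member of the interferon and antigen presentation lists rose. Of 21 interferon response genes 21 rose (21 adjusted over the list alone; median 2.68, adjusted p = 1.58e-29), among them Oasl2 by 3.75 ± 0.52, Gbp2 by 3.72 ± 0.46 and Gbp3 by 3.27 ± 0.40. Of 13 antigen presentation genes 13 rose (13 adjusted over the list alone; median 2.56, adjusted p = 6.63e-23), with the proteasome subunit gene Psmb9 up by 3.66 ± 0.40, the peptide transporter gene Tap1 by 3.48 ± 0.36 and B2m by 2.20 ± 0.26. Of 10 T cell genes 8 rose (8 adjusted over the list alone; median 1.86, adjusted p = 8.66e-08), including the granzyme genes Gzmb by 3.41 ± 0.70 and Gzma by 2.85 ± 0.57 and the T cell receptor gene Cd3d by 2.80 ± 0.62. Of 15 microglia genes 11 rose (12 rose and 1 fell adjusted over the list alone; median 0.70, adjusted p = 8.70e-13), led by Aif1 (1.89 ± 0.24) and the complement genes C1qa (1.56 ± 0.19), C1qb (1.49 ± 0.18) and C1qc (1.47 ± 0.18). Of 10 reactive glia genes 8 rose (9 adjusted over the list alone; median 0.86, adjusted p = 1.25e-10), among them C4b by 1.87 ± 0.17 and Osmr by 1.04 ± 0.15. Active CRHR1 array 2 had the lowest mean in its group on 4 of these 5 lists. Its mean over the T cell genes, relative to the Cre GFP mean, was 0.37 against 1.72 to 2.56 on the other 4 arrays and 0.86 on Cre GFP array 2, and over the antigen presentation genes it was 1.20 against 2.80 to 3.03. With slide as a block, which here equals the slide 2 arrays alone, the medians were 3.14, 2.93, 1.95, 0.84 and 0.98, and all 5 lists kept their call. With an estimated correlation none did, with adjusted p = 0.0792 for interferon response, antigen presentation and reactive glia, 0.127 for T cells and 0.117 for microglia.

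Genes of dividing cells and of immediate early responses were also higher. Of 15 cell cycle genes 12 rose (13 adjusted over the list alone; median 0.93, or 0.67 with members below background at their bound; adjusted p = 3.21e-14), among them Top2a by 2.26 ± 0.28, Ccnb2 by 1.00 ± 0.11 and Ccna2 by 0.98 ± 0.14. Of 24 immediate early genes 6 rose (11 adjusted over the list alone; median 0.60, or 0.56 with the bound; adjusted p = 1.35e-08). Atf3, also induced by cell stress, rose by 2.16 ± 0.27, Egr2 by 1.27 ± 0.35 and Nr4a1 by 1.18 ± 0.31. Of 16 apoptosis genes 2 rose, the death receptor gene Fas by 1.15 ± 0.20 and Pmaip1 by 1.39 ± 0.28 (3 rose and 1 fell adjusted over the list alone; median 0.12, adjusted p = 0.0224). Of 15 endothelial and mural genes 1 rose, Kcnj8 by 0.67 ± 0.13 (1 adjusted over the list alone; median 0.13, adjusted p = 0.000554). Under the slide block the 4 medians were 0.98, 0.52, 0.14 and 0.21, and apoptosis lost its call (adjusted p = 0.0558), as it did without Cre GFP array 1 (0.0693) or active CRHR1 array 1 (0.0694). The block also ended the calls of Kcnj8 (adjusted p = 0.0997), Egr2 (0.171) and Nr4a1 (0.174), and the latter 2 were lost in 8 of the 15 omissions each (up to 0.0893 and 0.0767). For the 4 lists, adjusted p = 0.0792, 0.128, 0.203 and 0.191 with an estimated correlation. With arrays centred on their median the medians of apoptosis and of endothelial and mural genes were 0.03 and 0.04, and Kcnj8, Egr2 and Nr4a1 lost their calls.

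Synaptic and neuronal lists were lower by similar amounts in the active CRHR1 group. Of 20 GABA synapse genes 5 fell (14 adjusted over the list alone; median -0.23, adjusted p = 4.91e-06), among them the receptor subunit genes Gabra5 by 0.39 ± 0.08 and Gabra4 by 0.37 ± 0.08. Of 18 granule cell markers 5 fell (9 adjusted over the list alone; median -0.24, adjusted p = 9.93e-06), with Rgs4 down by 0.60 ± 0.06 and Dlx2 by 0.31 ± 0.07. Of 27 presynaptic genes 4 fell (8 adjusted over the list alone; median -0.23, adjusted p = 1.86e-05), led by Sv2c (-0.63 ± 0.12). Of 27 cAMP pathway components 6 fell (9 adjusted over the list alone; median -0.20, adjusted p = 3.06e-05), among them Akap5 (-0.38 ± 0.08), and of 36 excitatory postsynaptic genes 7 fell (13 adjusted over the list alone; median -0.19, adjusted p = 5.02e-05), among them Dlgap1 (-0.39 ± 0.07). Of 12 mitral and tufted cell markers 3 fell (8 adjusted over the list alone; median -0.24, adjusted p = 0.00179) and of 11 genes of cortical and anterior olfactory neurons 4 fell (4 adjusted over the list alone; median -0.19, adjusted p = 0.00220), with Tbr1 (-0.49 ± 0.09) on both lists. In the fit with the slide block the 7 medians were -0.26, -0.26, -0.25, -0.25, -0.20, -0.28 and -0.28, and all kept their call. With an estimated correlation, adjusted p = 0.127 for each list except mitral and tufted cells (0.191). With arrays centred on their median the excitatory postsynaptic and the cortical and anterior olfactory lists each had a median of -0.29, and Dlx2 lost its call.

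Neuropeptide, neuroblast and myelin genes were lower too. Of 17 neuropeptide genes 4 fell (1 rose and 8 fell adjusted over the list alone; median -0.31, adjusted p = 0.00322): Grp, Adcyap1 by 0.68 ± 0.11, Sst by 0.71 ± 0.16 and Pomc by 0.39 ± 0.08. Of 15 neuroblast genes 2 fell, Dlx2 and Igfbpl1 by 0.31 each (5 adjusted over the list alone; median -0.21, or -0.13 without Cre GFP array 5; adjusted p = 0.00226). Of 14 oligodendrocyte genes 3 fell (5 adjusted over the list alone; median -0.26, adjusted p = 0.00351), among them Mal by 0.65 ± 0.14 and Mobp by 0.82 ± 0.22. Blocked on slide, the medians were -0.38, -0.39 and -0.37, all 3 lists kept their call, and Sst (adjusted p = 0.167), Pomc (0.0784) and Grp (0.144) lost theirs. Igfbpl1 was lost with median centring and in 9 of the 15 omissions (adjusted p up to 0.121) and Mobp in 5 (up to 0.0936). With an estimated correlation, adjusted p = 0.313 for neuropeptides and 0.386 for the other 2 lists. The genes known to vary between mouse strains shifted up by the test (7 rose; 7 rose and 1 fell adjusted over the list alone; adjusted p = 0.00193, and 0.0792 with an estimated correlation), with a median of -0.03 and a mean of 0.93 (the median was 0.10 with slide as a block, -0.12 with arrays centred on their median and between -0.04 and 0.07 over the 15 omissions). Their risen members, such as H2-K1 (2.56 ± 0.31), Trim30d (2.94 ± 0.51) and Mx2 (1.72 ± 0.32), are immune genes.

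The 12 lists not shifted with active CRHR1 included targets of cAMP and CREB (23 tested, median -0.08, adjusted p = 0.695), where Pde10a fell by 0.63 ± 0.09, Adcyap1 and Sst fell, and Gadd45b rose by 0.36 ± 0.10 (2 rose and 5 fell adjusted over the list alone). The others were ensheathing glia (1 lower, of 10; adjusted p = 0.0541), astrocytes (Gjb6 -0.35 and Glul -0.35, of 12; 0.0541), oligodendrocyte precursors (Olig1 -0.23, Olig2 -0.33 and Bmp4 -0.27, of 8; 0.0554), heat shock (Hsp90aa1 -0.31, of 9; 0.0581), genes beside Crhr1 (2 rose and 3 fell, of 28; 0.0857), dopaminergic cells (Ddc -0.32 and Pbx3 -0.21, of 9; 0.151), glucocorticoid response (Gjb6, of 19; 0.212) and growth factors (Nrg1 -0.28, of 15; 0.552). Blood (median -0.24), choroid plexus (-0.22) and sensory neurons (-0.17) had 0 changed members. Among the genes beside Crhr1, Gfap, an astrocyte filament, rose by 0.86 ± 0.21, and Nsf fell by 0.45 ± 0.06 on 1 probe while a second gave 0.43. Adjusted over the list alone, genes higher and lower were 3 and 6 beside Crhr1, 0 and 3 for astrocytes, oligodendrocyte precursors and heat shock, 0 and 2 for dopaminergic cells, 0 and 1 for ensheathing glia and glucocorticoid response, and 0 for the other 4 lists. With slide as a block ensheathing glia (median -0.27, adjusted p = 0.00305), oligodendrocyte precursors (-0.27, 0.00367) and heat shock (-0.22, 0.0341) passed, as did astrocytes with arrays centred on their median (-0.28, 0.0396), and Pde10a, Adcyap1, Ddc, Gfap and Nsf kept their calls. Pde10a, Adcyap1, Sst and Nsf held in all 15 omissions, the other genes being lost in 2 to 11 (adjusted p up to 0.123). Median centring ended the calls of Gadd45b, Ddc, Pbx3, Nrg1, Olig1, Olig2, Bmp4, Glul, Hsp90aa1 and Gfap.

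The comparison of active CRHR1 with knockout bulbs spans the extremes of signalling, but it also spans both strains, and no slide held both groups. Crhr1 was higher by 0.56 ± 0.09 (adjusted p = 0.00138), Crhbp by 0.80 ± 0.14 (adjusted p = 0.00191; 0.216 with slide as a block), and Crh differed by -0.21 (adjusted p = 0.393). Krt12 was at least 44.1-fold and Car6 at least 25.9-fold higher in the active CRHR1 group. Cst7 (4.82 ± 0.48), Nlrc5, an activator of class I genes (4.09 ± 0.44), H2-Q5 (3.96 ± 0.55), Eps8l1 (3.87 ± 0.64) and Pttg1 (3.87 ± 0.22) were higher too, and Npy2r was at least 2.17-fold lower. These calls held in all 15 omissions and, apart from Crhbp, with slide as a block. Pou6f1 (at least 45.5-fold higher), Cxcl9 (4.03), Hist2h2bb (-3.44), Tescl (-3.31), Fam227b (-3.29), Gbp2b (-3.20), Tmprss11d (-2.87) and Serpina1c (-2.59) held in all omissions but not with the block (adjusted p from 0.0557 to 0.261). Gdpd3 (3.99), Arhgap33os (-3.28), Zfp42 (-3.20) and Prg2 (-2.92) held in neither, being lost in 11, 8, 4 and 8 omissions (adjusted p up to 0.111, 0.0877, 0.0704 and 0.102).

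In all, 7063 genes passed, 2589 higher and 4474 lower with active CRHR1 (36.7% higher, and 48.1% of 4287 with arrays centred on their median or 47.8% of 4428 in the authors' scaled values). By at least 2-fold, 806 were higher and 243 lower. The arrays of the groups did not overlap for 4442 of them (62.9%). The count was 677 with slide as a block, 631 of them shared and 47.1% higher. It fell to 4176 without knockout array 4, 4217 without active CRHR1 array 1 and 4245 without active CRHR1 array 5.

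Immune lists were again higher in the active CRHR1 group and glial lists of myelin and olfactory axons were lower. Of 21 interferon response genes 21 rose (median 2.11), of 13 antigen presentation genes 12 (1.79), of 10 T cell genes 5 (1.17), of 10 reactive glia genes 5 (0.55), and of 15 microglia genes 8 rose and 2 fell (0.45). Gbp2 rose by 3.45 ± 0.46, Tap1 by 2.94 ± 0.36, Gfap by 1.67 ± 0.21 (other probes 0.49 and 0.28) and C1qa by 1.36 ± 0.19. Adjusted over the list alone 21, 13, 8, 7 and 11 rose, and 2 microglia genes fell. Of 15 cell cycle genes 9 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.64, or 0.53 with the bound), with Ccnb2 up by 0.82 ± 0.11 and Ccnd2 down at -0.61 ± 0.07. Of 14 oligodendrocyte genes 10 fell (11 adjusted over the list alone; median -0.49), such as Mog by 0.73 ± 0.14, and of 10 ensheathing glia genes 7 fell (8 adjusted over the list alone; median -0.41), such as Ngfr by 0.99 ± 0.11 and Frzb by 0.47 ± 0.08. Adjusted p ran from 8.96e-17 for interferon response to 0.000493 for T cells, and with an estimated correlation it was 0.388 or, for microglia, T cells and oligodendrocytes, 0.428. Under the slide block the medians of the 8 lists in this order were 3.13, 2.26, 1.32, 0.69, 0.64, 0.33, -0.73 and -0.65, and all kept their call.

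Of 27 cAMP pathway components 15 fell and 1 rose (15 and 1 adjusted over the list alone; median -0.25, adjusted p = 0.00257), with Rgs4 down by 0.80 ± 0.06, Akap5 by 0.49 ± 0.08 and Rapgef3 up by 0.38 ± 0.06. Other shifted lists were immediate early genes (4 rose of 24, 2 adjusted over the list alone; 0.35), strain variants (7 rose and 2 fell of 20, 8 and 2 adjusted over the list alone; 0.40), cortical and anterior olfactory neurons (5 fell of 11, 6 adjusted over the list alone; -0.31), mitral and tufted cells (4 fell of 12, 6 adjusted over the list alone; -0.25), neuroblasts (2 fell of 15, 2 adjusted over the list alone; -0.16), GABA synapse (6 fell of 20, 7 adjusted over the list alone; -0.12), excitatory postsynapse (3 rose and 10 fell of 36, 4 and 11 adjusted over the list alone; -0.16) and presynaptic genes (1 rose and 5 fell of 27, the same adjusted over the list alone; -0.21). In the fit with the slide block the medians were -0.28 for the cAMP list and 0.31, 0.27, -0.39, -0.34, -0.53, -0.19, -0.18 and -0.26 for the rest, and all kept their call. With an estimated correlation adjusted p ran from 0.340 to 0.605 over the 17 shifted lists. Without knockout array 1 the neuroblast, GABA, excitatory and presynaptic calls were lost (adjusted p = 0.0519, 0.0970, 0.160 and 0.160). That of GABA synapse was also lost without knockout array 4 (0.0650) or active CRHR1 array 1 (0.0665) or 5 (0.0669), that of excitatory postsynapse without knockout array 2 (0.0635) or active CRHR1 array 1 (0.0870), and that of presynaptic genes without knockout array 4 (0.0618) or active CRHR1 array 1 (0.0665) or 5 (0.0648). With arrays centred on their median the excitatory and presynaptic calls were lost (0.0511 each) and astrocytes passed (median -0.21, adjusted p = 0.0470). The median of immediate early genes was 0.21 without knockout array 1 and 0.19 without knockout array 2, and that of strain variants 0.26 without active CRHR1 array 5. With the block Rapgef3 lost its call (adjusted p = 0.0884). Among the 15 lists not shifted (adjusted p from 0.0535 to 0.932), 5 of 15 growth factor genes fell, with Igfbp5 at -0.71 ± 0.06 and Cntf at -0.67 ± 0.08, and 2 rose (5 and 2 adjusted over the list alone), and of 17 neuropeptide genes 5 fell, with Npy at -0.69 ± 0.10, and 1 rose (6 and 1 adjusted over the list alone). Neuropeptides (median -0.17, and -0.34 with the block) and oligodendrocyte precursors (-0.21 and -0.38) passed with slide as a block (adjusted p = 0.00962 and 0.00479). Glucocorticoid response genes differed in sign between median (-0.09), mean (0.0067) and test (up).

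Genes ordered by the strength of signalling were few. Of the 138 genes past the threshold in both comparisons with Cre GFP, 31 changed in opposite directions, 4 rising and 27 falling from low to high signalling, and the others in the same direction, 57 higher and 50 lower. The named genes with the largest opposed changes were Nell2 (0.86 in the knockout and -1.15 with active CRHR1), Rgs14 (0.70 and -0.71), Vxn (0.57 and -0.66), C1ql1, a synapse organiser (0.56 and -0.49), and Fxyd7 (0.59 and -0.49). In the knockout Rgs14 lost its call in 7 of the 15 omissions (adjusted p up to 0.0715) and Vxn in 12 (up to 0.113). Blocked on slide, Nell2 and Vxn kept both calls. Independent lists of these sizes would share 40.1 genes with opposite and 39.0 with equal signs. Unchanged groups, simulated with control arrays shared by both comparisons, gave 0 of either. Where no gene changed almost none is called, so this 0 is no chance value for the opposed genes. With the control arrays split between the comparisons the means of 20 splits were 1.20 (range 0 to 12) and 2.05 (range 0 to 11). The opposed count was 3 with arrays centred on their median (0 rising and 3 falling), 5 in the authors' scaled values (1 and 4), 20 with slide as a block (6 and 14) and 1, Nell2, within slides. With median centring the knockout calls of Rgs14, Vxn and C1ql1 were lost. The count fell to 14 without knockout array 2, 11 without knockout array 4, 10 without Cre GFP array 3, 6 without Cre GFP array 4, 11 without Cre GFP array 5, 12 without active CRHR1 array 1 and 18 without array 4 or 5 of that group.

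Across genes, which are not independent replicates, the changes of the knockout and of the active CRHR1 group against Cre GFP correlated with Pearson's r = 0.21 (jackknife SE 0.15 over arrays) and Spearman's rho = 0.07. Shared control arrays alone gave a mean r of 0.50 (range -0.18 to 0.85) in 100 simulations of unchanged groups. The covariance was 0.0323, against 0.0248 simulated, a difference of 0.00753. With the controls split, r averaged 0.07 (range -0.12 to 0.24), and with slide as a block it was -0.04. Without knockout array 3 it was 0.12.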

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

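The tests of strain differences, mirrored receptor loss, the immune genes on slide 2, unchanged microglia and dilution were chosen only after the result was seen, and the bound for mirrored loss was tightened after its value was known. An earlier test of unchanged microglia on 11 chosen genes was dropped, since the choice of genes set its outcome. A single array stood apart from the other 4 of its group in 40 of 537 groups of values, its gap to the nearest exceeding 0.71 of the group's range, where chance alone picks out about 1 in 20 groups. Each value in parentheses is that gap as a share of the range. Knockout array 1 was lowest for Hist2h2bb (0.783). Knockout array 2 was highest for the share of probes well above background (0.759), and lowest for the share of surrogate values (0.725). Knockout array 3 was lowest for Tmco5 (0.887) and the cortical and anterior olfactory neurons list (0.859). Knockout array 4 was highest for Ubd (0.713). Knockout array 5 was highest for Dlx2 (0.762), Egr2 (0.753) and Nr4a1 (0.723). Cre GFP array 1 was highest for Fam227b (0.960), Gbp2b (0.720) and the share of probes well above background (0.741), and lowest for the olfactory sensory neurons list (0.739). Cre GFP array 2 was highest for Acod1 (0.823), B2m (0.821), Cxcl9 (0.858) and the genes beside Crhr1 list (0.734), and lowest for Fxyd7 (0.797) and Homer3 (0.788). Cre GFP array 3 was lowest for Ccdc103 (0.727) and Pdgfrb (0.758). Cre GFP array 4 was lowest for Eps8l1 (0.757) and Pou6f1 (0.974). Cre GFP array 5 was lowest for Krt12 (0.841). Active CRHR1 array 2 was highest for Neu4 (0.719) and the share of surrogate values (0.794), and lowest for B2m (0.822), Cd3d (0.763), Cxcl9 (0.777), H2-K1 (0.904), H2-Q5 (0.915), Igfbp5 (0.772), Psmb9 (0.725) and the antigen presentation list (0.878). Active CRHR1 array 3 was lowest for Krt12 (0.773), Mog (0.721), Pou6f1 (0.855) and Tmco5 (0.730). Active CRHR1 array 4 was highest for Dlgap2 (0.737) and Pomc (0.749).

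Knockout bulbs differed from Cre GFP bulbs in 929 genes. A chance division of the arrays is argued against. In a fit of the 2 groups the real split gave 495 genes and the highest of the other splits 5 (1 of 100 as large, the real one). The other splits mix both groups, which widens their spread and lowers their counts, so they do not exclude chance by themselves. The median share of the change kept with slide as a block was 1.00. Calls made without slide favour genes that differ little between slides, so this share cannot exclude a difference between slides. With the block the count fell from 929 to 384. Variants under single probes are argued against for the 201 called genes with a second probe, which moved the same way in 87.6%. The share was 91.7% of 540 genes for active CRHR1 against Cre GFP, within 1 strain. For called genes without a second probe this was not tested. Differences between mouse strains stay open, and the position of the called genes goes with them. There were 1.91 times as many neighbouring pairs as in shuffles (55 against 28.8, at most 45 in 1000 shuffles). But pairs were also more frequent between active CRHR1 and Cre GFP, within 1 strain (1.39 times, 286 against at most 252). There the 5-Mb stretches with most calls lay on chromosome 17, from 30 and 35 Mb (31 of 117 and 25 of 101 genes). Most of these calls, 23 and 22, were rises. In the knockout they lay on chromosome 7, from 50 and 25 Mb (18 of 147 and 16 of 134, with 8 and 6 rises). In the first of these the knockout share was 12.2%, above that over all placed genes (724 of 17487). With active CRHR1 the same stretch held 19 of 147 (12.9%), near the share over all placed genes there (1926 of 17487). The stretch from 100 Mb on chromosome 11, which holds Crhr1, had 9 of 132 genes called in the knockout (6.8%). Whether both excesses of pairs share a source was not tested. Loss of the receptor, mirrored by its activation, also stays open, since on average 51.4% of the genes called in a split of the controls moved the opposite way when the comparisons used different control arrays, under the first bound of 55%, but single assignments of the arrays ranged from 44.0% to 59.8%. Of the 929 genes 39.3% did so (36.6% to 42.5%), but these were called with all 5 control arrays, which favours equal directions.

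Immune genes were higher in active CRHR1 bulbs, among 2339 changed genes. For these chance is argued against, with the same limit (2134 in the real split, at most 4 in the others, 1 of 100 as large). A difference between slides is argued against for 34 interferon and antigen presentation genes, which kept 119% of their median change among slide 2 arrays. The median share kept with the block over all called genes was 1.09, but calls made without slide favour such a share. More microglia of an unchanged state would raise no gene further than microglia markers. The median change of the 15 microglia markers was 26.9% of that of the 34 genes, where this explanation needs at least 75%. Of the 34 genes 27 rose further than the largest marker change, 1.89. The markers' mean lay below that of the 34 genes on 5 of 5 active CRHR1 arrays. These values argue against it as the whole cause for these genes. The 95% bootstrap interval, drawn over genes and not mice, was 7.35% to 56.7% and reached past the 50% set for excluding it. The labels give both groups the same injected volume and interval, so an injection as such does not set them apart. Whether the injections differed in their effect on the tissue was not measured. A response to the receptor or a difference between the virus preparations stays open and was not tested.

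Neuronal genes were lower in the same bulbs. Dilution by RNA of other cells, with the scaling of the arrays, is a candidate explanation. The median of 119 neuronal genes lay -0.041 from that of 32 astrocyte, sensory neuron and choroid plexus genes. The 95% bootstrap interval of this difference, drawn over genes and not mice, was -0.076 to 0.0076. The medians were -0.23 and -0.19, against -0.07 for all genes. But lists left out went both ways. Oligodendrocyte genes were lower (median -0.26). Endothelial and mural genes, which dilution alone would not raise, were higher (0.13, or 0.04 with arrays centred on their median). A change in the neurons themselves stays open and was not tested. For active CRHR1 against knockout, chance is argued against with the same limit (6188 genes in the real split, at most 17 in the others, 1 of 100 as large). The median share kept with slide as a block was 1.13 over the genes called without slide, but the count fell from 7063 to 677.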

How the results depend on the processing

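The leaving out of knockout arrays 2 and 5 and the brightest probe on the second probe's genes were chosen only after the results were seen. Crhr1 in the knockout kept its direction throughout but missed the threshold within slides (-0.56) and without knockout arrays 2 and 5 (-0.48). The correlation of the 2 changes turned to -0.0416 with slide as a fixed block and within slides. Lists shifted came to 0 in each comparison with the correlation estimated, to 3, 3 and 0 (active CRHR1 against Cre GFP, active CRHR1 against knockout, knockout against Cre GFP) with the second brightest probe (12 of the 32 lists could be tested, and the brightest probe of the same genes gave 4, 1 and 0), and in the knockout to 2 with fry and 13 with no filter on dim probes.

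Against 929 genes, the knockout gave 1404 with quantile normalization, 1562 with normexp, 459 with the authors' scaled values, 406 with median centring, 387 with no filter, 176 with the second probe, 384 with slide as a fixed block, 115 within slides, 495 with only the 2 groups, 1439 with array weights, 374 at 1.5-fold, 202 at an adjusted p under 0.01 and 333 without knockout arrays 2 and 5. Against 2339, active CRHR1 gave 1299 with the authors' scaled values, 1273 with median centring, 1246 with no filter, 477 with the second probe, 1018 with slide as a fixed block, 328 within slides, 5779 with array weights, 964 at 1.5-fold and 814 at an adjusted p under 0.01. Against 7063, active CRHR1 against knockout gave 4428 with the authors' scaled values, 4287 with median centring, 1372 with the second probe, 677 with slide as a fixed block, 10686 with slide as a random block (correlation -0.0566), 2540 at 1.5-fold, 2156 at an adjusted p under 0.01 and 3045 without knockout arrays 2 and 5. Opposed genes, 31 at first, came to 54 with normexp, 5 with the authors' scaled values, 3 with median centring and with no filter, 8 with the second probe, 20 with slide as a fixed block, 1 within slides, 9 with only the 2 groups, 75 with array weights, 4 at 1.5-fold, 2 at an adjusted p under 0.01 and 13 without knockout arrays 2 and 5. The second probe was tested for 5182 of 27441 genes, in which the brightest probe gave 330 genes for the knockout, 928 for active CRHR1 and 1854 between the extremes, so that fewer genes tested account for part of the lower counts. Stricter thresholds lower counts by construction, and for the rest the cause was not tested.

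Replicate numbers paired no samples. Of 15 pairs of same-numbered arrays 3 had deviations correlated over 0.1 (range -0.219 to 0.405), and 4 of 15 arrays correlated best with their own number. With the number as a replicate block the counts were 561, 1552, 6027 and 17 opposed.

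Some genes reversed between probes. With the second probe the changes were -0.46 (Ccdc103), 0.0091 (Dlgap2), 0.80 (Gfap), -0.0015 (Homer3) and -0.26 (Mbp) in the knockout, 0.52 (Dlgap2) and 0.43 (Nsf) with active CRHR1, and 0.56 (Homer3), 0.12 (Mbp), 0.66 (Nsf), 1.13 (Stmn1) and -2.97 (Xaf1) between the extremes. With the mean of probes they were -0.0013 (Ccdc103) and -0.015 (Mbp), 0.11 (Dlgap2), and 0.050 (Homer3), 0.095 (Nsf), 0.32 (Stmn1) and -0.27 (Xaf1), and Xaf1 was -3.01 in the authors' scaled values. Over the genes named by the rule, 20 values reversed, 5398 kept direction and side of the threshold, 989 lost it and 119 gained it, and for lists 1366 kept it, 100 lost it and 74 gained it.

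Leaving out each array gave Crhr1 changes of -0.51 to -0.42, 0.05 to 0.15 and 0.52 to 0.60, a correlation of 0.118 to 0.274, 7 to 11, 20 to 25 and 13 to 19 lists, 433 to 959, 1191 to 3671 and 4176 to 7941 genes (knockout, active CRHR1, and between the extremes) and 6 to 37 opposed genes. A random block cannot enter camera and was not run for lists, and no slide holds both extremes. Only 58.7% to 66.9% of probes were well above background, which limits dim genes.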

Other observations

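The gene lists and the genes named in this part, with all their tests, were chosen only after the results were seen. Several genes of an amino acid stress response driven by the factor ATF4 rose in active CRHR1 bulbs. Of 24 such genes 10 rose and 0 fell against Cre GFP (median 0.20, higher in 5 of 5 arrays; adjusted p = 0.0169 over 7 lists with an estimated correlation). The median was 0.099 with arrays centred on their median and 0.25 with slide as a block, where the estimated correlation gave an adjusted p of 0.0532. Trib3, a stress-induced pseudokinase, rose by 2.26 ± 0.15 and Slc7a3, an arginine transporter, by 2.05 ± 0.12, followed by Stc2 (0.82 ± 0.16), Mthfd2 (0.81 ± 0.13), Chac1 (0.70 ± 0.12) and Shmt2 (0.65 ± 0.07). Interferon-induced GTPases rose in 13 of 14 cases (median 3.36, and 3.74 with the block; adjusted p = 0.0169, and 0.0283 with the block), with Igtp up by 4.13 ± 0.45, and chemokines in 12 of 16 (median 2.70, and 3.28 with the block; 0.0175 and 0.0283), with Ccl2 up by 3.85 ± 0.49 and Ccl5 by 3.68 ± 0.59. Of 18 genes of activated microglia 10 rose (median 0.60, and 0.57 with the block; 0.0169 and 0.0357), among them Itgax by 2.82 ± 0.33 and Tlr2 by 1.65 ± 0.24. Each of these 3 lists was higher in 5 of 5 arrays, and 2 of the GTPases and 1 of the chemokines stand on lists fixed earlier. At least Cxcl9, Cxcl10, Cxcl13, Tgtp1 and Cst7 had been seen to rise before these lists were drawn up. Their tests are therefore not independent of genes seen earlier. Of 5 B and plasma cell genes 2 rose (median 1.02, higher in 5 of 5 arrays; 0.0339), a call lost with the block (median 1.06, 0.0614) and without Cre GFP array 1 (0.0623). Of 11 genes of resting microglia, 6 of them on earlier lists, 3 rose and 1 fell (median 0.17, and 0.071 with median centring, higher in 3 of 5 arrays; 0.279). Adjusted over these 7 lists together with the 32 fixed earlier, none passed in active CRHR1 against Cre GFP with an estimated correlation (adjusted p = 0.0536 for the stress, GTPase, chemokine and activated microglia lists, 0.0859 for B and plasma cells). Against the knockout the smallest adjusted p of the 7 lists with an estimated correlation was 0.0881.

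In knockout bulbs, 8 of 12 mural cell genes, which mark pericytes and vascular smooth muscle, rose and 0 fell (median 0.50, the same with slide as a block, higher in 5 of 5 arrays; adjusted p = 0.00342 over the 7 lists with an estimated correlation, and 0.00197 with the block). Among these 8, at least Rgs5, Kcnj8, Abcc9 and Pdgfrb had been seen to rise before the list was drawn up. The list's test is not independent of genes seen earlier. Without the 6 genes that stand on lists fixed earlier 3 of 6 rose (median 0.50), and adjusted p was 0.0361 over the 7 lists and 0.201 over all 39. Notch3 rose by 0.52 ± 0.06, Ndufa4l2 by 0.52 ± 0.08 and Vtn by 0.48 ± 0.09, the last losing its call with arrays centred on their median (adjusted p = 0.140). In active CRHR1 bulbs 2 of the 12 rose (median 0.04, or -0.05 with median centring; adjusted p = 0.130). For the other 6 lists in the knockout, adjusted p ran from 0.292 to 0.602 with an estimated correlation. Some genes changed alike in both groups against Cre GFP, whose arrays both comparisons share. Fgr, a kinase of myeloid cells, rose by 1.23 ± 0.13 in the knockout and 1.91 ± 0.13 with active CRHR1, and Pdcd1, an inhibitory receptor of T cells, by 1.59 ± 0.25 and 2.08 ± 0.25. Chil1 rose by 1.00 ± 0.09 and 0.41 ± 0.09 and Bhmt changed by -1.12 ± 0.16 and -0.67 ± 0.16, and with slide as a block both kept their call in the knockout but not with active CRHR1 (adjusted p = 0.0616 and 0.113), where Chil1 also lost it with median centring (0.125). The calls of the genes named in this part held when any 1 of the 15 arrays was left out, except that of Pdgfrb in the knockout, which was lost in 5 of the 15 omissions (adjusted p up to 0.0808), with slide as a block (0.0505) and with median centring (0.216).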
